A study of Mus musculus with 10 samples.

How the data were processed

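Chromatin accessibility was measured by ATAC-seq in naive CD4 T cells sorted from spleen and lymph node of mice that carry floxed Satb1 alleles and a Cre recombinase fused to a mutant oestrogen receptor under control of CD4. The 10 libraries were made from 60000 cells each, per the labels' protocols, with an in-house Tn5 transposase, and sequenced as single reads of 75 bp. The labels put 5 libraries in the group called KO here, from mice given tamoxifen, and 5 in the group called WT, from untreated mice of the same genotype. KO and WT libraries therefore differ in tamoxifen exposure as well as in Satb1 deletion, and no WT library was exposed to tamoxifen. The labels name the libraries by running numbers (Sample_2268_KO to Sample_2272_KO and Sample_2273_WT to Sample_2277_WT), which pair no library of one group with one of the other. They do not say whether each library came from a separate animal, so p-values measure the spread between these libraries, and they give no sex, litter or batch.

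The deposited table of the authors holds whole-number read counts, not normalized, for 61581 peaks of 1 common peak set, of which 10 are mitochondrial. A second deposited file gives the position, annotation class, nearest gene and distance to its transcription start site for the 61571 nuclear peaks. Per the submitters' processing notes, reads were handled with bcl2fastq 2.20, Trimmomatic 0.36, Bowtie2 2.3.5, Picard, SAMtools 1.9, deepTools 3.5.2 and 3.3.0, MACS2 2.1.2, R 3.5.3, ChIPseeker 1.18.0 and DESeq2 1.22.2 on mm10. Whether reads were shifted to the transposase cut site, how duplicates were treated, and whether peaks were called on pooled or single libraries is not given in the sources used here. A shift would move a peak's borders by a few bases and change few counts, whereas removal of duplicates caps the count of dense peaks in deep libraries. In 7971 peaks the annotation gives a gene number but no symbol. RefSeq names (assembly GRCm38.p6) matched 7932 of these, and gene sums used the deposited symbols only. The annotation assigns a peak to its nearest gene, which is not evidence that the peak acts on that gene.

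Total counts in peaks ranged from 673398 (Sample_2270_KO) to 2184717 (Sample_2272_KO), with a mean of 1474689 ± 649293 (SD, n = 5) in KO and 1653141 ± 413841 (SD, n = 5) in WT. The median peak held 5 to 17 counts per library, so most peaks carry a counting error that is large beside small changes.

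Peak counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3 (glmQLFit and glmQLFTest, TMM scaling, filterByExpr by group, no covariate), with Benjamini-Hochberg adjustment over the 34910 tested peaks and a threshold of 0.05. The other 26671 peaks had counts too low to test. Levels are counts-per-million (CPM) of the TMM-scaled in-peak total, given as mean ± SD over 5 libraries, and log2 fold changes are KO against WT with their SE. Folds of peaks and genes are edgeR's fitted values, in which a small prior count lowers the fold of a peak near 0 in 1 group. The SE was derived from the F statistic of the test and the log2 fold change without that prior count. It is therefore approximate for the printed value, most of all for such peaks. Peaks are called separated where the log2 CPM (prior count 2) of all KO libraries lie on one side of all WT libraries. For genes, counts of all peaks annotated to one symbol were summed and fitted the same way (12489 genes tested). The 20 gene lists were tested on the gene fit with camera of limma 3.58.1, which asks whether a list's genes shift against all other genes, with a preset correlation of 0.01, and again with an estimated correlation. Sums per library and annotation class means were compared with two-sided exact permutation tests over all 252 assignments of 5 libraries, whose smallest possible p is 0.00794. Coordinates are mm10 as deposited.

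The lists were: SATB1 targets named in thymus and T cell studies; IL-2 signalling; Th17, Th1, Th2, Tfh and Treg programmes; naive T cell and quiescence genes; activation and memory genes; T cell receptor and co-receptor signalling; inhibitory receptors; interferon response; oestrogen receptor response; CD8 T cell and cytotoxic genes; markers of B cells, of myeloid cells, of NK and innate lymphoid cells and of erythroid and stromal cells; housekeeping genes; and chromatin organisers and SATB1 partners. Members absent from the annotation used, Rora, Il17f and Ccr6 among them, were not analysed here. Values of 1 gene of the naive T cell list are not reported here, though the counts of that list include it. Named items follow a fixed rule. It takes up to 10 tested peaks each of Satb1 and Il2 by adjusted p. It takes the 12 largest fold changes per direction among separated called peaks, 1 per gene, without Gm, LOC, Rik and missing symbols. It takes up to 4 members per list with the smallest adjusted p of the gene fit, and the 10 called list genes per direction with the smallest adjusted p of the peak fit. Lists, rule, the tests of the report and all but 3 of the alternatives were set before the data were examined.

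The fit was tested on simulated counts with the real peak means and library sizes, 200 changed items and a dispersion of 0.01. For KO against WT over 34522 simulated tested peaks it recovered 35.8% of 1.5-fold, 70.1% of 2-fold and 83.3% of 4-fold changes, with 8.03% false calls. Over 12440 genes it recovered 71.6%, 94.0% and 100%, with 5.85% false calls. The simulated dispersion was larger than the common dispersion of the data (0.00273), so these recoveries reflect that spread as well as depth.

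Replicates were compared by a chi-square over 20129 nuclear peaks with a mean count of at least 20. In 12 of the 20 within-group pairs the counts differed by no more than Poisson noise (chi-square per degree of freedom 0.875 to 1.33 over all 20 pairs, median 1.01), against 1.06 to 1.64 between groups. Neither this noise nor the different totals shows whether libraries are separate samples, since copies of 1 library sequenced to different depths could give both. Some pairs lay below Poisson noise (0.875 for Sample_2268_KO with Sample_2270_KO and 0.882 for Sample_2274_WT with Sample_2275_WT), for which the cause was not tested. All 10 libraries were kept, so every n counts libraries that may not be independent. A fit with libraries within Poisson noise merged was added after the data were seen. Fits on counts thinned to the smallest total and without the 3 smallest libraries were added then too. Alternatives tried were DESeq2 1.42.0, RLE factors, total count scaling, loess offsets (span 0.5), other count filters, limma-voom, a robust fit, autosomes only, 1 surrogate variable (svaseq of sva 3.50.0), other thresholds, promoter peaks only, a 100 kb window around Il2, and each library left out. Motif tests of 18 fixed consensus strings and a GC correction need the genome sequence and were not run.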

Results

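ATAC-seq, in which a transposase cuts and tags open chromatin, was used to compare naive CD4 T cells (CD25-negative, CD44-low) with and without Satb1. SATB1 is a chromatin organiser that binds AT-rich DNA and is abundant in thymocytes and T cells. In the KO group tamoxifen had activated a Cre recombinase that deletes floxed Satb1 in CD4-expressing cells, and the WT group consisted of untreated mice of the same genotype. Each group had 5 libraries. Counts in peaks totalled 1390607 in Sample_2268_KO, 1053601 in Sample_2269_KO, 673398 in Sample_2270_KO, 2071124 in Sample_2271_KO and 2184717 in Sample_2272_KO. They totalled 1025283 in Sample_2273_WT, 1966906 in Sample_2274_WT, 2081740 in Sample_2275_WT, 1563101 in Sample_2276_WT and 1628674 in Sample_2277_WT. The series asks what Satb1 does to Il2 accessibility and IL-2 signalling when naive cells begin to become Th17 cells.

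The targeted gene was examined first. Satb1 lies on the minus strand of chromosome 17, from 51736187 to 51833290, and 16 of its 26 annotated peaks held enough counts to test. None was lower in KO by edgeR, DESeq2 or limma-voom (1 at an unadjusted p under 0.05), and 4 were higher. The largest change was in a distal intergenic peak past the 3' end of the gene (51732582 to 51732928), at 34.7 ± 4.77 CPM in KO and 14.1 ± 2.42 CPM in WT (SD, n = 5), a 2.32-fold rise (edgeR adjusted p = 6.04e-09). A 5' UTR peak (51826423 to 51826825) rose 1.55-fold, a promoter peak (51832493 to 51832893) 1.31-fold and an intronic peak (51813881 to 51814068) 1.77-fold. The promoter peak over the start site (51832905 to 51833388) stood at 61.6 ± 4.25 CPM in KO and 59.5 ± 6.54 CPM in WT and did not pass the test. Summed over all its peaks, Satb1 had 428 ± 12 CPM in KO and 373 ± 15.6 CPM in WT (SD, n = 5), with every KO library above every WT library (1.15-fold, two-sided exact permutation p = 0.00794, the smallest possible). The labels do not say which part of Satb1 is floxed, and accessibility of the rest of the gene need not fall with its deletion, so these peaks do not check the group labels. DESeq2 called 2 of the 4, the distal and the 5' UTR peak. The promoter call ended without Sample_2269_KO, Sample_2272_KO, Sample_2274_WT or Sample_2277_WT (edgeR adjusted p 0.0512 to 0.0988) and the intronic call without Sample_2271_KO, Sample_2273_WT, Sample_2275_WT or Sample_2276_WT (0.0512 to 0.503). Without Sample_2271_KO the intronic log2 fold change was 0.45 instead of 0.82. The promoter call also ended without a count filter (0.0540) and with thinning to the smallest total (0.530), which ended the 5' UTR call too (0.275). The intronic call also ended with limma-voom (0.0823). Both the promoter and intronic calls ended without the 3 libraries with the lowest totals and with libraries within Poisson noise merged (0.0664 to 0.163).

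**Figure D1:**
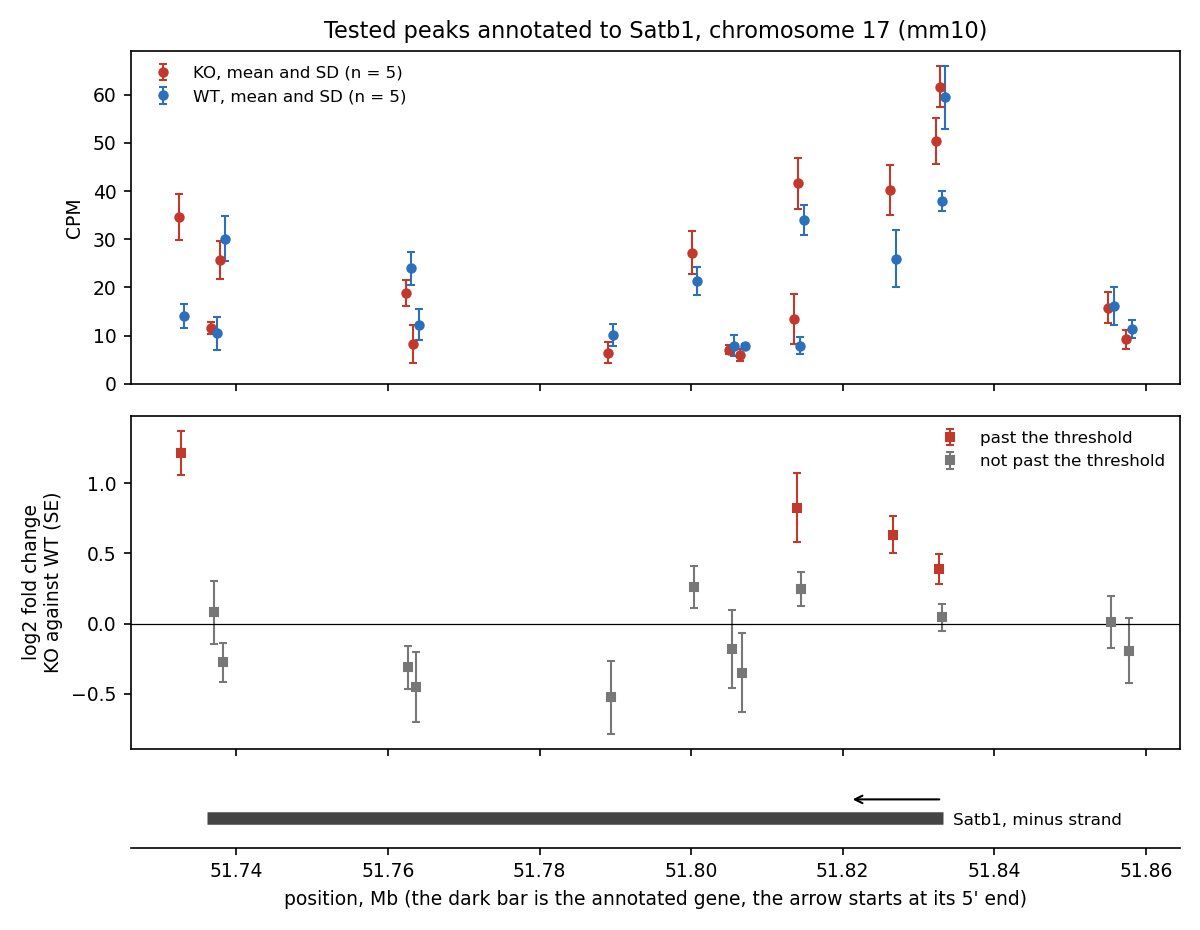
Peaks annotated to Satb1 on chromosome 17 (mm10, position in Mb), with CPM per group as mean and SD over 5 libraries (top, KO and WT points set slightly apart) and the log2 fold change of KO against WT with its SE (middle) above the annotated gene. The distal peak at the left edge, at 34.7 CPM in KO and 14.1 CPM in WT, has the largest log2 fold change of the 4 past the threshold, and the peak over the start site is at 0.04.

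Accessibility of the Il2 promoter was several-fold higher in KO. Il2 encodes interleukin-2, the growth factor that activated T cells secrete, and lies on the minus strand of chromosome 3 from 37120713 to 37125954. The peak just upstream of its start site (37126181 to 37126516, annotated as promoter) had 29.3 ± 6.70 CPM in KO and 3.28 ± 0.984 CPM in WT (SD, n = 5), an 8.92-fold rise (log2 fold change 3.16 ± 0.24 SE, edgeR adjusted p = 4.88e-18). The peak over the start site (37125695 to 37125981) had 23.3 ± 3.08 CPM against 5.86 ± 1.14 CPM, a 3.85-fold rise (1.95 ± 0.22 SE, adjusted p = 9.91e-11). Both Il2 promoter peaks together reached 52.7 ± 7.24 CPM in KO and 9.15 ± 1.75 CPM in WT (5.76-fold, exact permutation p = 0.00794), and all 5 KO libraries lay above all 5 WT libraries.

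Farther from Il2 the change was smaller or not detected. A distal intergenic peak at -31135 bp from the start site (37157089 to 37157428) rose 1.76-fold (edgeR adjusted p = 0.0296), and the other 4 distal peaks of Il2 did not pass over all tested peaks. All distal peaks of Il2 together had 80.5 ± 15 CPM in KO and 67.6 ± 6.05 CPM in WT (1.19-fold, exact permutation p = 0.111, n = 5). Of the 15 tested peaks within 200 kb of the Il2 start site, both promoter peaks and the peak at -31135 bp were called. None of the 8 that belong to neighbouring genes was, with edgeR, DESeq2 or limma-voom or at an unadjusted p under 0.05. Adjusted over these 15 peaks alone, the distal peak at -47420 bp passed as well (1.38-fold, edgeR adjusted p = 0.0427). All peaks annotated to the nearby cytokine gene Il21, summed, had 111 ± 3.09 CPM in KO and 117 ± 10.1 CPM in WT (adjusted p = 0.641). The call of the peak at -31135 bp ended with DESeq2 and when Sample_2268_KO, Sample_2271_KO, Sample_2276_WT or Sample_2277_WT was left out (edgeR adjusted p 0.0791 to 0.196). Neither Il2 promoter peak reaches a mean count of 50, and both drop out of a fit with that minimum.

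**Figure D2:**
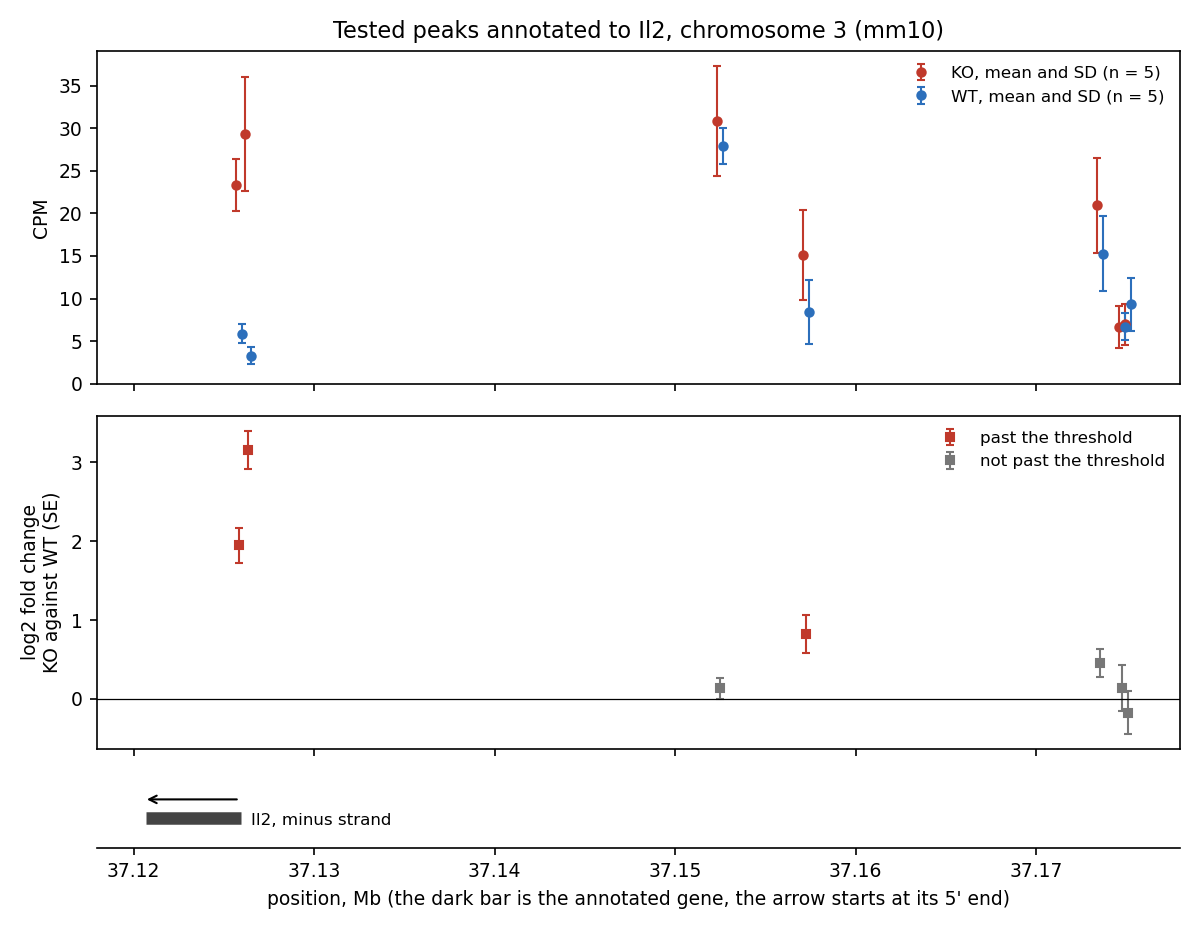
Peaks annotated to Il2 on chromosome 3 (mm10, position in Mb), with CPM per group as mean and SD over 5 libraries (top, KO and WT points set slightly apart) and the log2 fold change of KO against WT with its SE (middle) above the annotated gene. The 2 promoter peaks stand at 29.3 and 23.3 CPM in KO against 3.28 and 5.86 CPM in WT, while 4 of the 5 distal peaks are not past the threshold.

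Across the genome, 1345 of 34910 tested peaks (3.85%) differed between KO and WT, and most of them were more accessible in KO: 1027 rose and 318 fell. The rises were also larger. Of the peaks that rose 385 changed at least 2-fold and 65 at least 4-fold, against 35 and 1 of those that fell. The single 4-fold loss, named here after its value was seen, lay near 1700123K08Rik on chromosome 5 (138571743 to 138571908), at 1.54 CPM in KO and 8.97 CPM in WT. Over all tested peaks, called or not, the KO and WT libraries did not overlap in 3.96%, against 0.794% by chance. Among them were 717 of the higher and 157 of the lower peaks.

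The largest gains opened sites that were nearly closed in WT. An intronic peak annotated to Camk2d, a calcium- and calmodulin-dependent kinase (chromosome 3, 126825005 to 126825266), had 24.5 ± 8.65 CPM in KO and 1.00 ± 0.802 CPM in WT (SD, n = 5), a 22.8-fold rise (log2 fold change 4.51 ± 0.34 SE, edgeR adjusted p = 4.54e-18). A distal peak of Tm2d1 rose 13.8-fold, an exonic peak of Rexo5 12.2-fold, and intronic peaks of Dtd2 and Epsti1 11.4-fold and 9.97-fold. A peak at -64775 bp from Bcl2l11, in an intron of another gene, which encodes the death-promoting BCL-2 family member BIM, rose 9.42-fold from 4.14 ± 1.59 to 41.3 ± 6.33 CPM. Distal peaks of Ptprc, which encodes the receptor phosphatase CD45 (8.26-fold), and of Tnfsf18, which encodes the ligand of GITR (6.67-fold), also rose. So did peaks of Ppp1r3b, the integrin gene Itgb3 and the Mediator subunit gene Med30, by 7.51-fold, 6.68-fold and 6.59-fold.

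Losses left more signal behind. The 12 largest losses by the same rule, in peaks of Actr10, Wdr37, Prkar1a, Ube2e1, Ptpn13, Fanci, Urad, Olfr1510, AI837181, Fut8, Filip1l and Mocs2, were to 0.401-fold to 0.478-fold of the WT level. The distal peak of Wdr37, for example, fell from 19.4 ± 5.73 CPM in WT to 7.93 ± 1.07 CPM in KO (SD, n = 5, edgeR adjusted p = 1.29e-05), and a peak whose nearest start site, at 22355 bp, is that of Prkar1a, a regulatory subunit of protein kinase A, though it lies in an intron of another gene, fell from 21.8 ± 3.66 to 7.92 ± 3.74 CPM. The 12 gains were called by every alternative that tested them, whereas DESeq2, which called 529 peaks higher and 58 lower in all, called 7 of the 12 losses and not those of Urad, AI837181, Fut8, Filip1l and Mocs2. The AI837181 call also ended without Sample_2271_KO or Sample_2275_WT (adjusted p 0.0761 and 0.0620) and the Mocs2 call without Sample_2272_KO or Sample_2276_WT (0.104 and 0.0702).

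**Figure D3:**
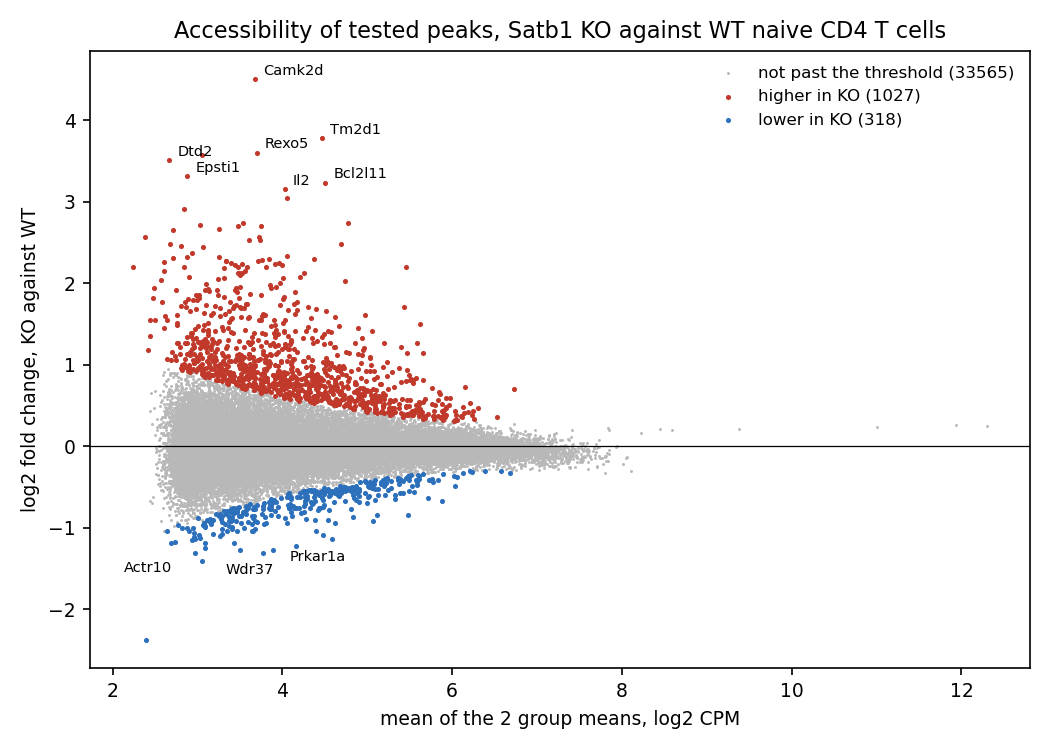
Log2 fold change of KO against WT for 34910 tested peaks, plotted against the log2 of the mean CPM of both groups; each point is a peak. Called peaks are coloured, 1027 higher and 318 lower in KO, and the labelled Camk2d peak has the largest fitted rise, 22.8-fold.

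**Figure D4:**
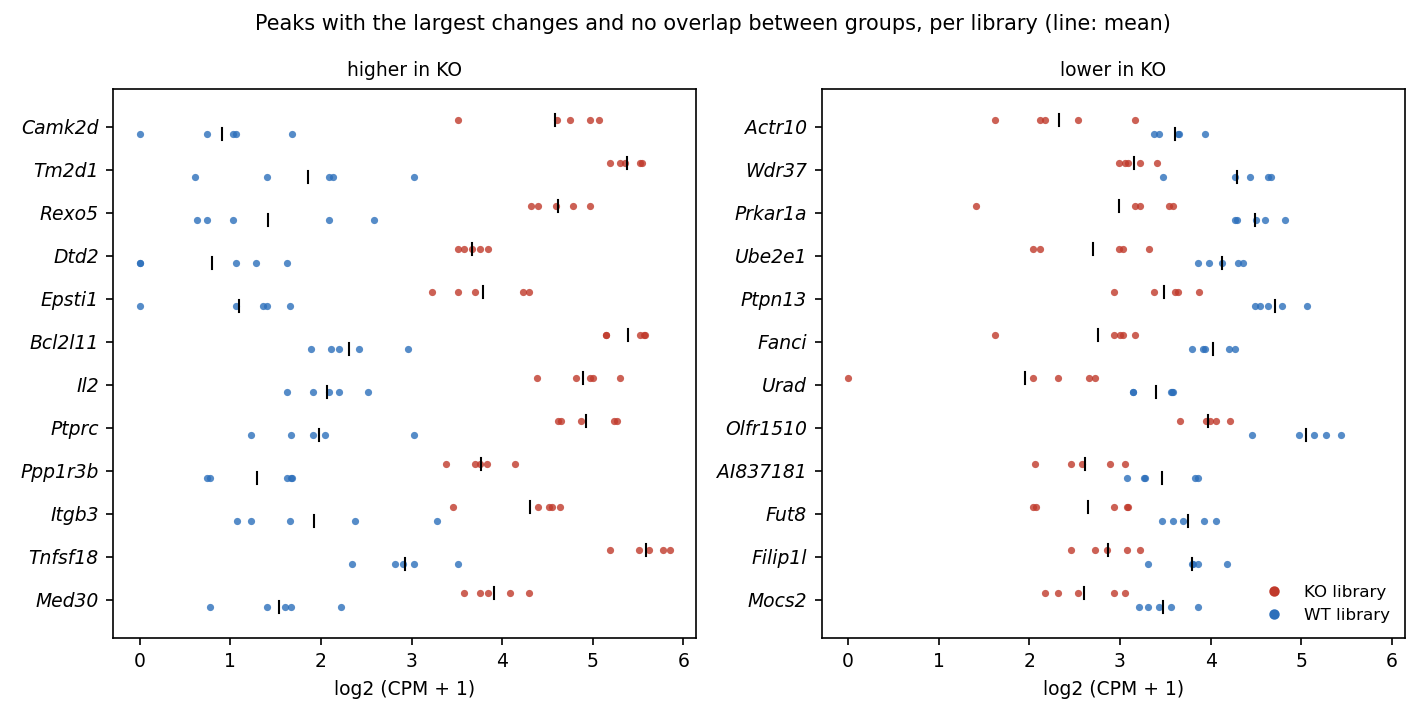
Accessibility of the 12 peaks with the largest rise and the 12 with the largest fall among called peaks whose groups do not overlap, taken 1 per gene without Gm, LOC, Rik and missing symbols. Values are log2 of CPM + 1, each point is a library and the line is the mean of 5. The peak of Tm2d1 went from a mean of 3.19 to 40.9 CPM, and that of Wdr37 from 19.4 to 7.93 CPM.

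The changes lay mostly away from promoters. Among 18753 tested peaks outside promoters 824 rose (4.39%) and 263 fell (1.40%), and among 16147 promoter peaks 203 rose (1.26%) and 55 fell (0.341%). A peak outside promoters was therefore more often called in either direction (odds ratio 3.61, 95% interval 3.09 to 4.24, for rises and 4.16, 3.10 to 5.68, for falls; Fisher's exact test across peaks, which are not independent replicates). Introns held 438 rises and 136 falls and distal intergenic regions 329 and 97. The upstream Il2 peak had the largest rise of any promoter peak, in a ranking made after the data were seen. As whole classes, promoters, introns, exons, untranslated, downstream and distal regions showed no detectable shift: the mean log2 CPM of each differed between KO and WT by less than the spread between libraries (exact permutation, Benjamini-Hochberg adjusted p = 0.992 for each of the 7 classes). With 5 libraries a side a shift of 1 class alone cannot pass this adjustment.

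**Figure D5:**
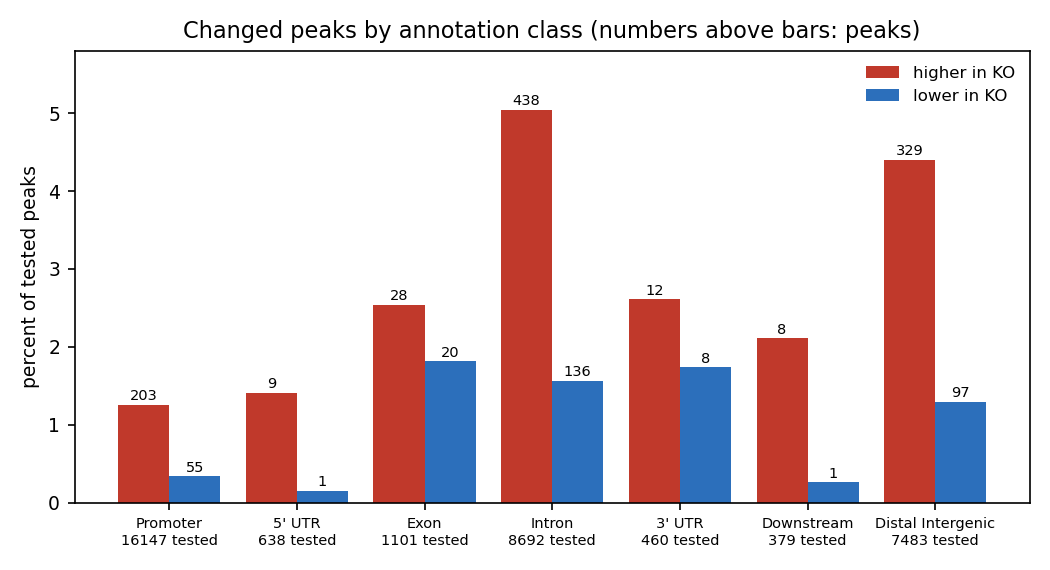
Percent of tested peaks of each annotation class that were higher or lower in KO; the number above each bar counts peaks and the axis starts at 0. Bars for introns reach 5.04% and 1.56% and those for promoters 1.26% and 0.341%.

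Summed per gene, 273 of 12489 genes changed, 206 upwards and 67 downwards. Arid5b, which encodes a DNA-binding regulator, held 7 higher peaks out of 15 tested and rose 1.53-fold as a gene (393 ± 35.8 against 258 ± 6.94 CPM, SD, n = 5, edgeR adjusted p = 1.53e-11). Fam49b held 5 higher and 1 lower peak out of 26, with a gene sum that did not pass (adjusted p = 0.945). Zfp608, Tox, Satb1 and Sesn3 held 4 higher peaks each and no lower one. Except for Tox and Satb1, these genes were chosen after their number of called peaks was seen.

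T helper cytokine and regulator loci gained accessibility at single genes. In the Th17 list 2 of 15 tested members rose, 3 adjusted over the list alone, and none fell: Basp1 (1.41-fold, edgeR adjusted p = 0.000931) and Il1r1, the interleukin-1 receptor (2.28-fold, 5.47 ± 2.04 to 12.7 ± 3.13 CPM, SD, n = 5, adjusted p = 0.00673). Maf and Il6st, a transcription factor and the shared signalling subunit of the IL-6 receptor, did not pass at gene level over all genes with edgeR, though Maf was the third to pass over the list alone (adjusted p = 0.00637) and passed with limma-voom (0.0412), and single distal peaks of theirs rose 4.74-fold and 3.35-fold. In the Th2 list 3 of 13 rose, also over the list alone: the cytokine gene Il4 (2.78-fold, adjusted p = 0.00024), none of whose peaks held enough counts to be tested singly, its regulator Gata3 (387 ± 30.2 against 325 ± 22.6 CPM, adjusted p = 0.00696) and Dusp6 (1.13-fold). No member of the Th1 list passed among 12 tested, by edgeR, DESeq2 or limma-voom (2 higher and 1 lower at an unadjusted p under 0.05). Adjusted over the list alone 1 did, Ifng, with 139 ± 11.3 CPM in KO and 118 ± 3.87 CPM in WT (adjusted p = 0.0577 over all genes), and 2 distal peaks of Ifng rose 2.81-fold and 3.29-fold (adjusted p = 7.29e-08 and 2.81e-06), named after their values were seen. In the Tfh list 1 of 13 members rose, Tox (1.23-fold), 2 adjusted over the list alone. Of its 100 tested peaks 11 rose and 2 fell, with a peak of Cxcr4 up 3.16-fold, where the share over all tested peaks would give 2.94 and 0.911. This share, here and for the lists below, is not matched on annotation class. Outside promoters peaks rose more often (4.39% against 1.26%), so part of such an excess may reflect where a list's peaks lie, which was not tested. In the Treg list Ctla4, an inhibitory receptor (1.39-fold, adjusted p = 5.93e-07), and the transcription factor gene Ikzf2 (1.28-fold) rose out of 16, the same 2 over the list alone, whereas Foxp3 had 9.03 ± 3.66 CPM in KO and 7.36 ± 1.69 CPM in WT (adjusted p = 0.498). Of 17 called list genes, 4 stayed called in every alternative that gave them a value. With DESeq2 the calls of Il1r1, Dusp6 and Ikzf2 ended. In promoter peaks alone and with libraries within Poisson noise merged, those of Gata3 (adjusted p = 0.898 and 0.519) and Tox (0.974 and 0.101) ended, and in promoter peaks alone that of Basp1 too (0.721). Both settings also ended the calls of Dusp6 (edgeR adjusted p = 0.689 and 0.516) and Ikzf2 (0.103 and 0.0896). Thinning to the smallest total ended these 2 calls (0.232 and 0.192), as did leaving out the 3 libraries with the lowest totals (0.0663 and 0.0989). Leaving out Sample_2271_KO, Sample_2272_KO, Sample_2273_WT, Sample_2275_WT, Sample_2276_WT or Sample_2277_WT ended that of Dusp6 (adjusted p 0.0647 to 0.236), and leaving out Sample_2272_KO, Sample_2274_WT or Sample_2275_WT that of Ikzf2 (0.0560 to 0.0726).

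Single peaks of these T helper lists also fell. They included the promoters of Ccr4 (Th2, 0.689-fold) and Capg (Treg, 0.702-fold), an intronic peak of Il12rb2 (Th1, 0.655-fold) and a distal peak of Bcl6 (Tfh, 0.571-fold). An exonic peak annotated to Irf4 (Th17, 0.587-fold) and another distal peak of Bcl6 (0.669-fold) fell too, and a peak annotated to Bcl6, in an intron of another transcript, rose 2.70-fold, these 3 named after their values were seen. DESeq2 called no peak of these lists lower, and limma-voom called neither the Irf4 peak nor the second of Bcl6. Leaving out Sample_2275_WT ended the calls of Capg and Ccr4 (adjusted p = 0.157 and 0.0514), and leaving out Sample_2268_KO, Sample_2271_KO, Sample_2274_WT or Sample_2276_WT that of the 0.571-fold Bcl6 peak (0.0538 to 0.114). Thinning to the smallest total ended those of Il12rb2, Capg and Ccr4 (0.395 to 0.731), leaving out the 3 libraries with the lowest totals that of Capg (0.114), and merging libraries within Poisson noise those of Ccr4 and Bcl6 (0.0607 and 0.0732).

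Within the IL-2 signalling list Il2 itself was the member that rose (1.74-fold over all its peaks, edgeR adjusted p = 8.8e-11), out of 17 tested and also over the list alone. The receptor gene Il2ra had 169 ± 20.8 CPM in KO and 166 ± 12.8 CPM in WT (SD, n = 5, adjusted p = 0.845), and Cish 105 ± 9.53 against 92.3 ± 11.2 CPM (adjusted p = 0.3). Of the 109 tested peaks of this list 7 rose, 3 of them of Il2, and 0 fell. The share over all tested peaks would give 3.21 higher and 0.993 lower.

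In the naive and quiescence list 3 of 21 tested members rose, among them Il7r, the receptor for the survival cytokine IL-7 (1.31-fold, edgeR adjusted p = 1.03e-06), and Satb1. Adjusted over the list alone 4 rose, S1pr1 being 1 of them, and Tcf7 fell. At single peaks 22 of 350 rose and 4 fell, where the share over all tested peaks, not matched on annotation class, would give 10.3 and 3.19. The peaks that fell were annotated to Ccr7 (2 peaks, the stronger at 0.726-fold), Tcf7 (0.758-fold) and Bach2 (0.494-fold), each of which is typical of naive cells. Bach2 also held 2 called peaks that were higher in KO (1.40-fold and 1.75-fold), and its gene sum did not pass (adjusted p = 0.898). DESeq2 called none of the 4 and called 12 peaks of this list higher; the Ccr7 call ended without Sample_2272_KO (adjusted p = 0.0521), that of Tcf7 without Sample_2268_KO, Sample_2271_KO, Sample_2274_WT or Sample_2275_WT (0.0753 to 0.204) and that of Bach2 without Sample_2272_KO, Sample_2274_WT or Sample_2275_WT (0.0856 to 0.104). The Il7r gene call ended in promoter peaks alone (adjusted p = 0.532). The Satb1 gene call ended with DESeq2 and without Sample_2268_KO, Sample_2271_KO, Sample_2273_WT or Sample_2276_WT (0.0580 to 0.0991). It also ended in promoter peaks alone (0.352), with thinning to the smallest total (0.543), without the 3 smallest libraries (0.114) and with libraries within Poisson noise merged (0.497).

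Among T cell receptor genes Trat1 (1.23-fold) and Ptpn22 (1.2-fold) rose out of 25, both also over the list alone, and 16 of 238 peaks rose with 0 lower. In the activation and memory list 1 of 29 rose, the chemokine receptor gene Cxcr6 (1.25-fold), and among inhibitory receptors 1 of 12, Ctla4, and both counts were the same adjusted over the list alone. DESeq2 called none of Trat1, Ptpn22 and Cxcr6. Their calls also ended in promoter peaks alone (adjusted p = 0.949, 0.764 and 0.949, in that order) and with libraries within Poisson noise merged (0.252, 0.320 and 0.164). Thinning to the smallest total ended those of Trat1 and Cxcr6 (0.420 and 0.310), and leaving out the 3 smallest libraries that of Ptpn22 (0.162). Leaving out Sample_2271_KO or Sample_2275_WT ended the call of Trat1 (adjusted p 0.0822 and 0.0549), Sample_2271_KO, Sample_2273_WT or Sample_2277_WT that of Ptpn22 (0.0698 to 0.0975), and Sample_2271_KO, Sample_2272_KO, Sample_2275_WT or Sample_2277_WT that of Cxcr6 (0.0532 to 0.131).

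As sets, 3 of the 20 lists shifted upwards against all other genes: SATB1 targets (camera adjusted p = 0.00112; 4 of 15 members rose, Ctla4, Il4, Tox and Ikzf2, the same 4 over the list alone), naive and quiescence genes (0.0323) and Tfh genes (0.0467). With an estimated correlation none of the 20 passed (adjusted p = 0.0521, 0.428 and 0.426, in the same order), and 1 had an unadjusted p under 0.05. Nor did the 3 pass with camera on peaks (0.0687, 0.452 and 0.125) or after thinning (0.103, 0.103 and 0.149). In promoter peaks alone the SATB1 (0.550) and Tfh (0.805) calls ended and the naive call stayed (0.00159). Merging libraries within Poisson noise ended the naive and Tfh calls (0.184 each). Of 100 groupings of the libraries, the real one among them, 18 gave at least 3 lists. With the preset correlation on genes the other T cell lists did not pass, among them Th2 (0.0563), Th17 (0.0758), Treg and inhibitory receptors (0.0967 each), and IL-2 signalling and T cell receptor genes (0.122 each). The lists overlap, since Ctla4 is in 3 of them and Tox in 2. In promoter peaks alone Ctla4, Tox and Cxcr6 had log2 fold changes of -0.059, -0.024 and -0.070, none past the test. Activation and memory genes (0.411), chromatin organisers and SATB1 partners (0.405, with Satb1 as the 1 riser of 21 and also over the list alone), Th1 genes (0.774) and housekeeping genes (0.502, with 0 of 18 past the test over all genes, over the list alone, by DESeq2 or limma-voom, and at an unadjusted p under 0.05) did not pass. The Th1 median (0.0018) and test pointed up and its mean (-0.0067) down. The naive and Tfh calls ended without Sample_2271_KO (adjusted p = 0.181 for both), Sample_2273_WT (0.132), Sample_2276_WT (0.0858) or Sample_2277_WT (0.128), which left 1 list past the threshold each time, while leaving out Sample_2270_KO gave 8, Sample_2269_KO or Sample_2274_WT gave 6 and Sample_2268_KO gave 5.

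Genes that respond to the oestrogen receptor, which tamoxifen binds, or to interferon did not pass as sets. In the oestrogen receptor list (camera adjusted p = 0.756) Ctsd, a lysosomal protease gene, fell to 0.806-fold (edgeR adjusted p = 0.0309) out of 12 tested, and the same 1 adjusted over the list alone. DESeq2 did not call the Ctsd gene, and its call ended without Sample_2271_KO, Sample_2272_KO, Sample_2274_WT or Sample_2277_WT (0.0788 to 0.163). The gene call also ended in promoter peaks alone (edgeR adjusted p = 0.176), with thinning to the smallest total (0.278) and with libraries within Poisson noise merged (0.164). At single peaks of this list a Ctsd promoter peak fell to 0.734-fold (edgeR adjusted p = 0.0295). Its call ended without Sample_2269_KO, Sample_2271_KO, Sample_2272_KO, Sample_2274_WT or Sample_2275_WT (0.0506 to 0.197). Thinning (0.407), leaving out the 3 libraries with the lowest totals (0.0541) and merging libraries within Poisson noise (0.110) ended it too. A distal peak of Nrip1, named after its value was seen, rose 2.49-fold (edgeR adjusted p = 0.000861), and DESeq2 called only the Nrip1 peak. The median of this list was 0.018 and its mean -0.017, with the test pointing down. Of the interferon list (camera 0.756) 0 of 24 passed with edgeR, DESeq2 or limma-voom (3 higher and 2 lower at an unadjusted p under 0.05), while adjusted over the list alone 2 were higher, Gbp3 (1.28-fold) and Ifit2 (1.21-fold), and 1 was lower, Oasl1 (0.827-fold).

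Summed markers of other cell types leaned in different directions between the groups, and no such list passed after adjustment, as a sum or with camera. Peaks of B cell markers summed to 270 ± 9.85 CPM in KO and 295 ± 12.1 CPM in WT (0.914-fold, exact permutation p = 0.0159, 0.0873 adjusted over 11 library checks, n = 5). Those of NK and innate lymphoid markers had 762 ± 27 CPM in KO and 681 ± 10.5 CPM in WT (1.12-fold, exact permutation p = 0.00794, adjusted 0.0873), with all 5 KO libraries above all 5 WT libraries. A single check cannot pass this adjustment over 11 even with complete separation. At single peaks 4 of 30 tested NK and 2 of 27 myeloid marker peaks rose (3 and 1 with DESeq2) and 0 fell. The share over all tested peaks would give 0.883 and 0.794 higher. Of 13 B cell marker peaks 0 changed with edgeR, DESeq2 or limma-voom (1 higher and 2 lower at an unadjusted p under 0.05). In the gene fit the 1 NK marker of 9 that rose was Klrb1b (1.43-fold, edgeR adjusted p = 5.64e-07), also over the list alone. Klrb1b held 3 of the higher NK peaks and went from 150 ± 10.1 CPM in WT to 223 ± 24.5 CPM in KO. That gap is most of the difference between the NK sums, so the NK sum rests mainly on 1 gene. Camera gave 0.0976 for NK and for myeloid markers, 0.122 for B cell, 0.75 for erythroid and stromal and 0.855 for CD8 and cytotoxic genes. None of the 11 myeloid, 6 B cell, 7 erythroid and stromal and 12 CD8 and cytotoxic genes passed over all genes with edgeR, DESeq2 or limma-voom. At an unadjusted p under 0.05, 1 myeloid gene was higher, and 2 B cell, 1 erythroid or stromal and 2 CD8 or cytotoxic genes were lower. Adjusted over the list alone, Bank1 and Cd83 of the B cell list were lower, Irf8 of the myeloid list was higher, and 0 of the other 2 lists passed. For NK markers the median was -0.029 and the mean 0.065, and for CD8 and cytotoxic genes the median was -0.055 and the mean 0.00083 with the test pointing down. A peak annotated to Prf1 of the cytotoxic list, in an intron of another gene, fell to 0.528-fold, and 1 peak of Fasl of that list rose. Of the housekeeping gene Ywhaz 1 distal peak fell to 0.533-fold and another rose 1.28-fold. The rising peaks were named after their values were seen. DESeq2 called none of these peaks. The Prf1 call ended without Sample_2269_KO, Sample_2272_KO or Sample_2275_WT (adjusted p 0.0541 to 0.103) and the Ywhaz call without Sample_2268_KO, Sample_2269_KO, Sample_2275_WT, Sample_2276_WT or Sample_2277_WT (0.0505 to 0.0588), and both without the 3 libraries with the lowest totals (0.119 and 0.109) or with libraries within Poisson noise merged (0.0552 and 0.0692). The share of counts in promoter peaks was 60.5% ± 1.07 in KO and 61.0% ± 1.25 in WT (SD, n = 5, exact permutation p = 0.524).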

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

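Of the tests in this part, the thinning of libraries was chosen only after the result was seen. A library was singled out where its gap to the nearest library of its group exceeded 0.71 of the group's range (Dixon's 95% limit for 5 libraries). This happened in 6 of 160 groups, and chance alone singles out about 1 in 20 groups, or 8 of 160. Principal components, the main axes of difference between libraries, were not among these groups. On the first, Sample_2270_KO lay at -68.3 and the other KO libraries at -21.1 to -7.95. Sample_2273_WT lay at 28.9 there, against 23.0 to 24.2 in the other WT libraries. On the second it lay at 21.1, against 6.76 to 10.1.

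Peaks of B cell markers summed to 252 CPM in Sample_2269_KO and to 272 to 277 CPM in the other KO libraries (gap ratio 0.804). The mean log2 CPM of 5' UTR peaks was 4.86 in Sample_2273_WT and 4.90 to 4.92 in the other WT libraries (0.748). The intronic Satb1 peak at 51800291 to 51800575 had 16.4 CPM in Sample_2276_WT against 21.7 to 23.6 CPM (0.734). In Sample_2270_KO, the library with the lowest total, the intronic Itgb3 peak had 10.0 CPM against 20 to 23.9 CPM in the other KO libraries (0.715), still above its WT mean of 3.49 CPM. In Sample_2269_KO the 5' UTR peak annotated to Fanci had 2.09 CPM against 6.67 to 7.98 CPM (0.778). The intronic Il12rb2 peak had 16.3 CPM in Sample_2273_WT and 31.5 to 37.2 CPM in the other WT libraries (0.726), so that Sample_2273_WT alone lay among the KO libraries, whose mean was 20 CPM. The Il12rb2 call stayed without Sample_2273_WT but ended with DESeq2 and with thinning to the smallest total.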

How the results depend on the processing

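Thinning of all libraries to the smallest total, leaving out the 3 libraries with the lowest totals and merging libraries within Poisson noise were chosen after seeing the data. Of the 1345 called peaks, 587 were shared in the same direction with DESeq2, 1328 with RLE factors, 1321 with total count scaling, 1314 with loess offsets and 1222 with limma-voom, and 0 were called in the opposite direction under any alternative. Summed Satb1 peaks (log2 0.18 to 0.21 with each library left out) and Il2 promoter peaks (2.41 to 2.59) kept their direction. The annotation class means gave 0 to 0 calls with each library left out, which says nothing about stability, since 1 shifted class alone could not pass there. With each library left out, changed peaks numbered 1096 to 1385, higher 780 to 1042, lower 243 to 352 and genes 191 to 259. Satb1 peaks numbered 3 to 4, Il2 peaks 2 to 3 and lists 1 to 8. Among named peaks 1142 comparisons kept direction and side of the threshold, 91 lost the call and 2 reversed; among named genes these were 1600, 62 and 9, with 17 newly past, and among lists 456, 23 and 13, with 27 newly past.

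At an adjusted p under 0.1 lower peaks numbered 538. Requiring a 2-fold change left 420 peaks (385 higher, 35 lower) and 21 genes, by construction fewer. DESeq2 called 587 peaks (529 higher, 58 lower), 109 genes and 2 Satb1 peaks; the cause was not tested. A mean count of at least 50, which removes both Il2 promoter peaks, left 158 peaks (123 higher, 35 lower), 1 Satb1 peak and 0 Il2 peaks, as fewer peaks were tested, and gave 5 lists, for which the cause was not tested. Promoter peaks alone gave 70 genes. The lists past the threshold numbered 0 with an estimated correlation, 0 with camera on peaks and 7 with 1 surrogate variable; the cause was not tested. Thinning, which lowers every count, left 273 peaks (230 higher, 43 lower), 85 genes and 0 lists. Leaving out the 3 smallest libraries gave 6 lists, and merging gave 164 lower peaks, 139 genes and 1 list from fewer libraries.

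The cause of the reversals was not tested. Camera on peaks turned the interferon (0.032) and housekeeping (-0.012) means. Promoter peaks alone turned Th2 (-0.032), inhibitory receptors (-0.048), B cell markers (0.15), Ctla4 (-0.059), Tox (-0.024), Il18r1 (-0.0059), Ccr8 (-0.12), Cxcr6 (-0.070) and Esr1 (-0.12), of which Ctla4, Tox and Cxcr6 were called over all peaks. A mean count of at least 50 turned the interferon list (0.0088). Thinning turned the test of the oestrogen list (mean -0.018), Col1a1 (0.062) and Rps18 (-0.080). Leaving out the 3 smallest libraries turned Th1 (-0.035), the Il2 peak at 37174973 (0.087) and Cdh5 (0.0073). With each library left out the CD8 and cytotoxic list ranged from -0.033 to 0.037, Th1 from -0.050 to 0.033 and the Il2 peak at 37174678 from -0.0082 to 0.22. Motif tests and their GC correction were not run, for lack of a genome sequence. Single peaks are limited by depth and spread, as 35.8% of simulated 1.5-fold changes were found at a dispersion of 0.01, which exceeds the 0.00273 of the data.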

Other observations

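Chosen only after the result was seen were the thinning of libraries, the comparison of neighbours matched by annotation class, the reading of their excess against the spread of random draws, the comparison within 10 kb, the shift of all neighbours, and the choice of the genes, peak groups and chromosomes described first. Slc38a1, an amino acid transporter gene, held 3 higher peaks and rose 1.36-fold as a gene (edgeR adjusted p = 1.87e-07). Zfp608 rose 1.40-fold (adjusted p = 1.27e-08), whereas Sesn3, with 4 higher peaks out of 12, did not pass as a gene (adjusted p = 0.108). At least 3 lower peaks were found in 1 gene, Sall3, and at least 3 higher peaks in 26. Of the 713 gene symbols with a higher peak and the 257 with a lower peak, 37 held both.

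Peaks that rose were weak in WT, with a median of 10.8 CPM in WT and 21.6 CPM in KO, and 52.9% of them lay in the lowest of 3 equal classes of WT level. Peaks that fell had a median of 24.3 CPM in WT and 15.3 CPM in KO, and 6.92% lay in that class. Their median distances to the nearest start site were 22177 bp and 20092 bp, against 4327 bp for peaks without a call. A peak measured low in WT by chance is more easily called higher in KO, so these WT levels are not independent of the calls. Chromosome 1 held 91 higher peaks out of 2179 tested (odds ratio 1.48, Fisher's exact test, adjusted p = 0.017 over 21 chromosomes), and chromosome 5 held 34 lower peaks out of 2161 (odds ratio 1.83, adjusted p = 0.0444). Each direction was adjusted by itself. The test treats peaks as independent, but neighbouring peaks changed together, so these p-values may be too small.

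A random grouping of these libraries is argued against for the peak count. The real grouping called 1345 peaks and the other 99 of 100 groupings at most 472 (1 grouping, the real one, reached the real count). It is argued against for genes as well (273, at most 94 otherwise, 1 of 100). Chance differences between animals are not covered, since the labels do not say whether libraries came from separate animals. For lists a random grouping cannot be excluded, as 3 passed and another grouping gave 9 (18 of 100 groupings reached 3).

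More peaks were higher than lower in KO, 76.4% of those called. The tables argue against the choice of scaling as the cause, as the lowest share under 3 other scalings was 72.9%. These 3 use counts in the same peaks and left the median log2 fold change of all tested peaks at -0.011 to -0.0057. They cannot show or exclude a shift shared by most peaks. The tables also argue against a single library, as the lowest share with 1 library left out was 71.2%. A depth difference is argued against only for the 273 peaks called after thinning to the smallest total, of which 84.2% were higher. Thinning lowers every count, so small changes are harder to call, and large ones were mostly rises (385 higher and 35 lower at 2-fold or more). For the other called peaks thinning therefore cannot decide. Loss of Satb1 may underlie the excess, but KO mice alone received tamoxifen, so deletion and drug exposure cannot be separated in this design.

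Changed peaks lay away from promoters. A smaller chance of detecting change in dense promoter peaks is argued against by peaks matched on count and density, whose common odds ratio was 2.95 with a lower bound of 2.56. A different background of the libraries is argued against by the difference between the class medians of log2 fold change, 0.00233 in size. It may be that Satb1 loss acts mostly on distal elements, a hypothesis that again cannot be separated from tamoxifen.

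Neighbouring peaks changed together. Pieces of 1 element called as several peaks allow no excess beyond 10 kb. At 10 to 100 kb 5.85% of tested neighbours of changed peaks were changed, against 4.04% (SD 0.187 over random draws) around peaks matched on count. Matched on annotation class too, it was 4.33% (SD 0.187). The ratio of 1.45 to the former stayed below the limit of 1.5 set beforehand, so by that limit such pieces are not settled. The excess over the spread of random draws argues against them, in a reading chosen after the result was seen. Random peaks were drawn singly while changed peaks cluster, so that spread may be too small. Within 10 kb, at a ratio of 2.02, such pieces cannot be told apart from separate elements, since both allow an excess. Uneven depth along chromosomes is argued against, as all tested neighbours of higher peaks at 10 to 100 kb, called or not, had a median log2 fold change of 0.0073 and those of lower peaks -0.029, against 0.88 and -0.69 for the called peaks. Shared direction (77.2% of changed neighbours at 10 to 100 kb, with 32.1% of the changed neighbours of lower peaks lower) decides nothing here, because uneven depth would also move neighbours the same way.

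Mitochondrial counts lay between 13291 and 18360 in all 10 libraries, which were 0.780% to 1.97% of their totals. None of the 10 mitochondrial peaks was called by edgeR, DESeq2 or limma-voom, or had an unadjusted p under 0.05.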
